A study of Mus musculus with 48 samples.

How the data were processed

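Polyadenylated RNA of sorted CD4 and CD8 T cells was sequenced by the authors in 48 libraries, and the deposited files, 1 per library, give read counts per Ensembl gene, raw counts with no normalization. The submitters' processing notes name STAR 2.5.2 and the genome build GRCm39; the counting tool, the annotation release and the strand setting are not given in the sources used here. The reference at hand holds another build, so no gene coordinates are given and genes are identified by symbol and Ensembl identifier. July files list 41256 genes and June files 44494; the 38356 genes in both were used, which left out at most 0.0228% of a library's counts, and 36526 of them have a symbol (10 symbols occur more than once). CPM are counts divided by the library total after TMM scaling, times 1e6. The scaling is over the libraries of a fit in its comparison, and over all 48 for library measures (summed markers, Xist, LN isotype M123) and in the closing part, so values of a gene can differ. A gene with 0 counts in every library of a group is given as a bound computed at 3 counts per library; such bounds and CPM values carry counting error only for reads, which are not independent molecules.

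Groups were taken from the labels as tissue, cell type and treatment. Replicates are separate mice, 17 in all, which tumor and lymph node libraries share. June mice carry the numbers 1 and 2 only, assumed to be other mice in each treatment and the same across tissues and cell types. Residuals of equally numbered libraries (r -0.0280 to 0.0392, 11 pairs of groups) cannot test this, as libraries of a July mouse gave -0.0429 to 0.0108. The unreplicated library labelled LN CD4 T cells after ICB and CD40 activation entered no comparison. Groups, tests, gene lists, named genes and the alternatives in the closing part on processing, except those said there to be added later, were chosen before the data were examined.

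Each comparison was tested with edgeR 4.0.16 (quasi-likelihood test, TMM, filterByExpr with a minimum count of 10 and a minimum total of 15, terms for group and batch) in R 4.3.3. Libraries of a tissue and cell type were fitted together, those of both tissues or both cell types together for the tissue comparisons and the interactions. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called. There were 16 comparisons, 12 of treatments, and p-values are not adjusted across comparisons. The 30 gene lists were written from textbook knowledge and tested where at least 3 members passed the filter, with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists of a comparison. They were also tested with an estimated correlation and with fry, which asks whether a list's genes move, on balance, in 1 direction. List medians are on the log2 CPM scale, and no called list had a median, mean and test of differing sign. Of 104 list calls over all comparisons, 17 held with estimated correlation and 53 with fry.

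Genes are named by rule. The rule takes, per comparison, the 8 largest higher and the 8 largest lower log2 changes among called genes with a mean log2 CPM of at least 2 and the same direction in both batches, without immunoglobulin and T cell receptor segments, mitochondrial genes and unnamed gene models. It adds up to 4 members with the smallest p from each list described, and a fixed set of genes of T cell state. Where fewer than 4 genes are called, the 4 with the smallest p are named as not passing. Mitochondrial and Y-linked called genes outside the rule were named after their values were seen.

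The correlation of the ICB effect with the CD40 effect is across genes, from batch-adjusted means of log2 CPM, with a two-sided permutation p from 100 seeded regroupings of libraries within batch. The pipeline was tested on simulated counts with the spread of these data and 200 changed genes per comparison. A log2 change of 2 was recovered for 3, 7, 2, 5 and 0% of genes and one of 4 for 20, 30, 23, 17 and 13% (tumor CD8 ICB against isotype, LN CD8 CD4-depleted against ICB, tumor CD4, CD8 tissue, tissue interaction), with 0 false calls. A proliferation list moved by 1 was called in all of these but the interaction. A low count of called genes here therefore leaves most changes of these sizes undetected.

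The alternatives were DESeq2 1.42.0, RLE scaling, no filter on low counts, no batch term, each batch alone, the compared groups alone, a block for the replicate number or the mouse, each library left out, and for the correlation Spearman's rho and genes of a log2 CPM of at least 4. Limma-trend and others named in the closing part on processing were added after seeing the data.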

Results

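RNA was sequenced from T cells sorted out of mice that carried transplanted colorectal tumors lacking DNA mismatch repair, the system that corrects copying errors in DNA. CD4 T cells, which help and regulate immune responses, and CD8 T cells, which kill target cells, came from the tumor or from the tumor-draining lymph node (LN). The wild-type Balb/c OlaHsd mice were given isotype control antibodies or checkpoint blockade (ICB). Blockade here means antibodies against PD-1 and CTLA-4, receptors that restrain T cells. Further mice were given ICB while an antibody removed their CD4 T cells (CD4-depleted ICB), or this combination plus an antibody that activates CD40, the receptor through which CD4 T cells help antigen-presenting cells (CD40 group). Treatment began at tumor volumes of 100 to 120 mm³ and ran for 3 doses at intervals of 3 days. Tissue was taken 48 hours after the last dose.

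The 48 libraries fell into 13 groups. CD8 T cells of tumor and LN were each sequenced under all 4 treatments, with 4 libraries per group apart from the 3 LN libraries of the CD40 group. CD4 T cells of tumor and LN were sequenced under isotype and ICB with 4 libraries each. A further library was labelled as LN CD4 T cells after ICB and CD40 activation, had no replicate and entered no comparison. Samples were handled in 2 batches, June and July, with 24 libraries each and 2 libraries of most groups in each. Total counts per library ran from 5965048 to 16099449 with a median of 10968738. Values below are CPM, counts scaled to the same library total, as mean ± SD with n = 4 per group, or n = 3 for the LN CD40 group. Log2 changes carry their standard error (SE).

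Xist, the RNA that silences an X chromosome in female cells, separated the treatments in every tissue and cell type. It stood at 76.7 CPM or more in each of the 32 libraries of treated mice and at 0.516 CPM or less in each of the 16 isotype libraries, while the summed RNA of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d was at least 12.2 CPM in isotype and at most 17.2 CPM in treated libraries. Every comparison of treated with isotype mice below carries this difference.

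**Figure D1:**
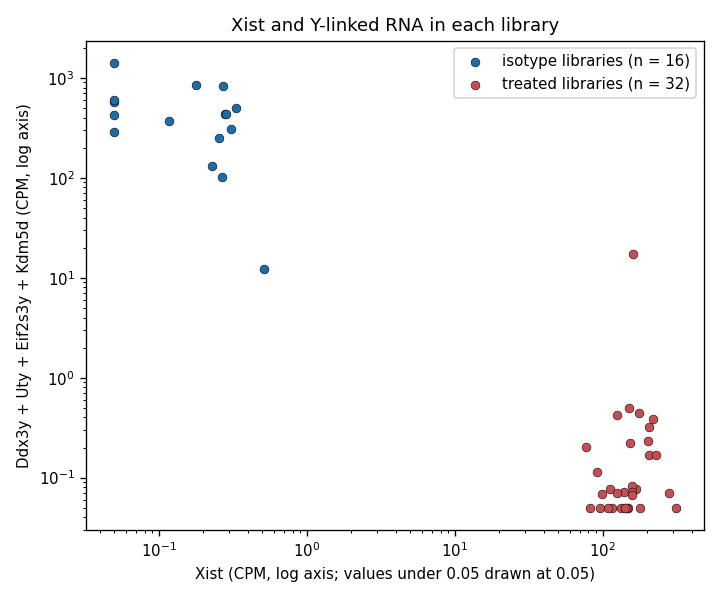
Xist against the summed RNA of the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d, both in CPM on log axes, with a point for each of the 16 isotype and 32 treated libraries. Every isotype library lies at or below 0.516 CPM of Xist and every treated library at or above 76.7 CPM.

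RNA of the T cell receptor complex, the marker of T cells themselves, varied most among isotype tumor libraries. In tumor CD8 cells its summed level averaged 2268 CPM under isotype (194 to 5170) and 3020 CPM under ICB (2636 to 3349). In tumor CD4 cells the levels were 1033 CPM (352 to 2408) and 1572 CPM (1064 to 1946). Mitochondrial genes, listed to gauge RNA quality, took 8.92% of counts under isotype and 2.69% under ICB in tumor CD8 cells. The shares were 7.19% and 2.83% in LN CD8, 9.07% and 4.55% in tumor CD4, and 10.4% and 6.16% in LN CD4 cells. RNA quality and treatment cannot be told apart as the source of this difference. In 5 isotype tumor libraries, CD8 mice 1 and 2 and CD4 mice M122, M123 and 1, macrophage and monocyte RNA exceeded receptor complex RNA by more than 4 times. Without Spp1, which tumor cells can make as well, this held for CD8 mouse 1 (7.59 times) and CD4 mouse 1 (4.16), with ratios of 0.823 to 3.90 in the others.

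The comparison of ICB with isotype in tumor CD8 cells asks what the blockade did to T cells at the tumor site. Ccr2 (ENSMUSG00000049103), a chemokine receptor that directs leukocytes to inflamed tissue, rose from 135 ± 83.9 CPM (68.8 to 258) under isotype to 865 ± 200 CPM (676 to 1054) under ICB. The log2 change was 2.70 ± 0.41 (adjusted p = 0.0206), with 3.01 in June and 2.64 in July. Ccpg1 (ENSMUSG00000034563), a receptor for autophagy of the endoplasmic reticulum, rose from 0.0565 ± 0.0669 to 34.4 ± 7.07 CPM (log2 8.92 ± 1.38, adjusted p = 0.0206). Xist (ENSMUSG00000086503) rose by log2 9.66 ± 0.80 (adjusted p = 1.61e-05). The mitochondrial gene mt-Cytb (ENSMUSG00000064370) fell from 27175 to 5508 CPM (log2 -2.26 ± 0.29, adjusted p = 0.00309). Genes of killing and exhaustion did not pass the test. Gzmb, a granule protease, stood at 458 under ICB against 398 CPM under isotype (log2 0.54 ± 0.74), and Prf1, which forms pores, at 48.4 against 218.5 CPM (-1.80 ± 1.41, June 4.05, July -3.42). Pdcd1, the gene of PD-1, had a log2 change of 0.76 and Tox, a factor of exhaustion, one of -0.32. The cytokine receptor gene Il7r stood at 379 against 91.4 CPM (2.15 ± 0.88), the cycling marker Mki67 at 17.4 against 80.8 CPM (-2.59 ± 1.11) and Cd8a differed by -0.08 ± 0.57. In all, edgeR called 3 genes higher and 1 lower of 11292 tested (1079 at unadjusted p under 0.05). Limma-trend called 39, DESeq2 492, the June libraries alone 24 and the July libraries alone 0. The count was 33 without isotype M122, 8 without isotype M123 and 2 without ICB M217, M218 or 2. Ccr2 lost its call without ICB M217 (adjusted p = 0.0813), M218 (0.0600) or 2 (0.0580), or isotype 1 (0.0770) or 2 (0.106), as did Ccpg1 with p from 0.0600 to 0.106. The Ccr2 call was also lost with the pair of groups fitted alone (0.091) or without isotype mice 1 and 2 together (0.173).

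Among the gene lists for this comparison, 8 of 25 were called by camera, 0 with estimated correlation and 5 by fry. The proliferation list, genes of DNA replication and mitosis, fell in 29 of 30 members (median log2 -1.63, adjusted p = 1.63e-05; 0.133 with estimated correlation). Pcna stood at 50.9 under ICB against 127 CPM and no member passed when adjusted over the list alone. Genes induced by type I interferon, the antiviral cytokine, rose in 22 of 26 members (median 2.05, adjusted p = 1.63e-05, and 0.133 as adjusted p with estimated correlation), with Cmpk2 at 64.2 against 0.399 CPM and Zbp1 at 106 against 43.8 CPM. Costimulation and cytokine receptors rose in 19 of 23 (median 1.63, adjusted p = 7.95e-07; 0.161 with estimated correlation). Adjusted over the list alone 2 members passed, Ifngr1, a chain of the interferon gamma receptor (4837 against 1993 CPM, log2 1.43 ± 0.33), and Il18rap, a chain of the interleukin 18 receptor (980 against 185 CPM, 2.52 ± 0.61). The Th1 list rose in 10 of 13 (median 1.51, adjusted p = 0.00114; 0.161 with estimated correlation), with Il18rap as its member passing over the list alone. The interferon gamma list rose in 22 of 26 (median 1.45, adjusted p = 0.00114; 0.513 with estimated correlation). Its median was 0.0691 in July alone and -0.0732 without isotype mice 1 and 2. Homing and residency genes rose in 10 of 14 (median 0.35, adjusted p = 0.0381; 0.415 with estimated correlation), with Ccr2 passing over the list alone. CD8 lineage genes rose in 4 of 5 (median 1.30, adjusted p = 0.0452; 0.520 with estimated correlation). Their median was 0.14 in July alone and 0.0346 without isotype mice 1 and 2. All 7 mitochondrial genes fell (median -1.70, adjusted p = 3.69e-07; 0.161 with estimated correlation), and all 7 passed over the list alone. Without isotype 1 the interferon gamma (adjusted p = 0.232), homing (0.307) and CD8 lineage (0.612) calls were lost. The homing (0.104) and CD8 lineage (0.0862) calls were lost without ICB 2, and that of CD8 lineage without ICB 1 (0.102). Without the high-ratio isotype mice 1 and 2, 2 lists were called.

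The same blockade in mice without CD4 T cells was compared with ICB to ask what CD4 cells contribute to tumor CD8 cells. Cycling genes, T cell receptor signalling genes and stress genes were higher in the CD4-depleted mice, and no gene alone passed the test. B cell markers were higher too, at 129 to 240.5 CPM summed against 0.535 to 22.6 CPM, with too few past the filter for a list test. The proliferation list rose in 27 of 30 members (median log2 1.09, adjusted p = 3.27e-05; 0.161 with estimated correlation). Mcm2, a part of the replication helicase, stood at 146 against 45.8 CPM and Mki67 at 76.7 against 17.4 CPM. Immediate early and heat shock genes rose in 18 of 20 (median 0.63, adjusted p = 0.000834; 0.230 with estimated correlation). The chaperone gene Hspa1b stood at 91.0 against 18.7 CPM and Hsph1 at 414 against 195 CPM. Genes induced by T cell receptor signalling rose in 16 of 18 (median 0.70, adjusted p = 0.0352; 0.705 with estimated correlation), with Nr4a1 at 209 against 75.5 CPM. No member of these 3 lists passed over the list alone. Tox stood at 473 against 143 CPM (log2 1.73 ± 0.81) and Il7r at 126 against 379 CPM (-1.56 ± 0.85), neither past the test. The smallest p-values were those of Igkc, an antibody light chain gene of B cells (40.8 ± 23.1 against 0.0712 ± 0.0530 CPM, adjusted p = 0.263), and the kinase gene Mapk14 (0.505 against 72.3 CPM). Next were the mitotic motor gene Kif4 (62.1 against 0.0205 CPM) and Man2a1, at least 46.9-fold lower with 0 counts in every CD4-depleted library. edgeR called 0 genes (669 at unadjusted p under 0.05), limma-trend 3 and DESeq2 251. With estimated correlation or by fry 0 lists were called. The T cell receptor signalling call was lost without ICB M217 (adjusted p = 0.0735), M218 (0.228) or 1 (0.0879), or CD4-depleted M224 (0.165), 1 (0.175) or 2 (0.278).

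CD40 activation on top of CD4 depletion was compared with CD4 depletion alone to ask whether CD40 signalling stands in for CD4 help. It shares the CD4-depleted libraries with the comparison before, so opposite changes in both are no sign of a reversal. Proliferation genes fell in 28 of 30 members (median log2 -1.24, adjusted p = 1.2e-05; 0.127 with estimated correlation), with the nucleotide synthesis gene Rrm2 at 22 against 79.8 CPM. A single member passed over the list alone, the mitotic checkpoint gene Bub1 (0.0541 against 35.1 CPM, -9.19 ± 2.20). Immediate early and heat shock genes fell in 15 of 20 (median -0.58, adjusted p = 0.00376; 0.365 with estimated correlation). Hsph1 stood at 157 against 414 CPM and Hspa1b at 20.8 against 91.0 CPM, and 0 members passed over the list alone. Furin, a protease that processes cytokine precursors, stood at 309 against 87.9 CPM (1.85 ± 0.41) and the chaperonin gene Hspd1 at 59.8 against 181 CPM (-1.57 ± 0.35, adjusted p = 0.704). Alg10b stood at 0.0382 against 51.9 CPM and Man2a1 was at least 74.1-fold higher. Pdcd1 stood at 750 against 454 CPM (0.78 ± 0.59), Gzmb differed by -0.06, and none of these genes passed the test. edgeR called 0 genes (663 at unadjusted p under 0.05), limma-trend 0 and DESeq2 288. Lists called were 0 with estimated correlation or fry. The stress gene call was lost without CD40 M232 (adjusted p = 0.0602) or 2 (0.0555), or CD4-depleted 1 (0.0871).

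Against ICB with CD4 cells present, camera with the preset correlation called 3 lists as higher in tumor CD8 cells of the CD40 group. Summed B cell markers were higher too (28.8 to 192 against 0.535 to 22.6 CPM). The type I interferon list rose in 22 of 26 members (median log2 0.63, adjusted p = 0.0488; 0.793 with estimated correlation), with Ifi27l2a at 222 against 83.0 CPM. Receptor signalling genes rose in 17 of 18 (median 0.68, adjusted p = 0.00963; 0.793 with estimated correlation), with a log2 change of 0.94 for the costimulatory receptor gene Tnfrsf9. CD4 lineage genes rose in 4 of 4 (median 1.64, adjusted p = 0.0488; 0.434 with estimated correlation). No member of the 3 lists passed over the list alone. The smallest p-values were those of Igkc (log2 8.55 ± 1.49, adjusted p = 0.319), Wwtr1 (6.80), Gm44226, at least 27.7-fold lower, and Mettl22, at least 6.08-fold lower. edgeR called 0 genes (573 or 5.07% at unadjusted p under 0.05), limma-trend 1 and DESeq2 94 higher and 124 lower. Neither estimated correlation nor fry left a list called (0). Each list call was lost without ICB M218 (adjusted p up to 0.259) or CD40 mouse 1 (up to 0.511). The interferon call was also lost without CD40 M232 (0.145) or M234 (0.0907) or ICB M217 (0.274) or 2 (0.0545). That of receptor signalling was lost without CD40 2 (0.0768), and that of CD4 lineage without CD40 M232 (0.145) or 2 (0.0768) or ICB 1 (0.219) or 2 (0.0918).

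**Figure D2:**
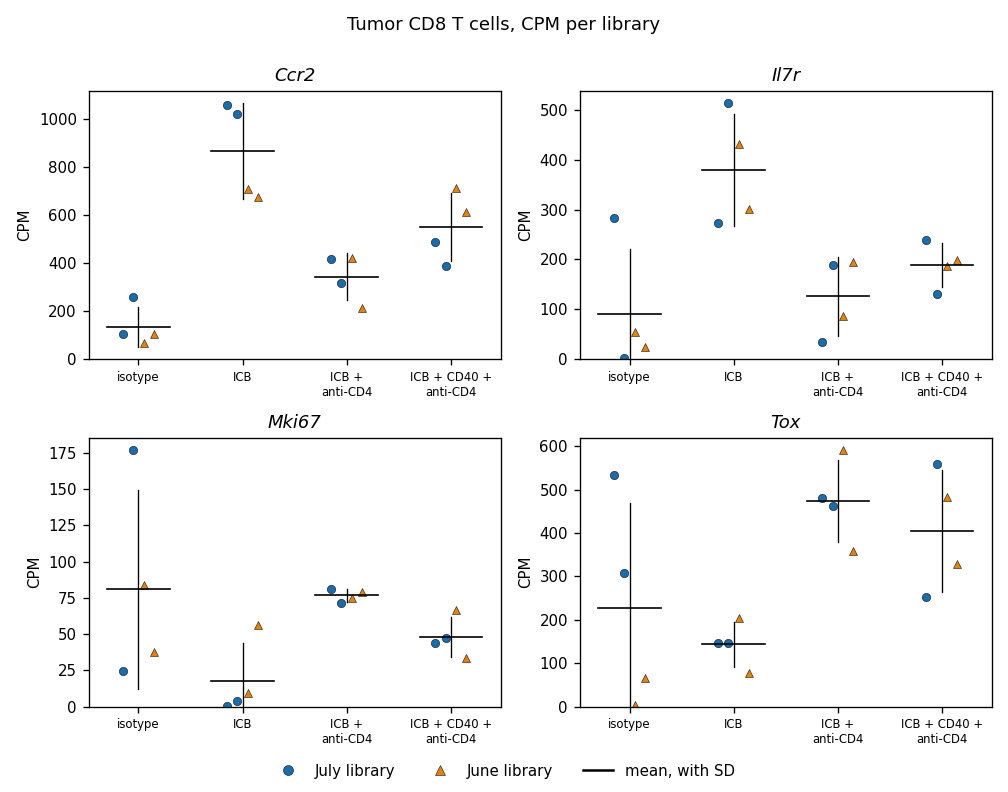
CPM of Ccr2, Il7r, Mki67 and Tox in each tumor CD8 library by treatment, with circles for July, triangles for June, lines for group mean and SD. Ccr2 lies between 676 and 1054 CPM in the ICB libraries and between 68.8 and 258 CPM in the isotype libraries.

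CD4-depleted ICB was also set against isotype in tumor CD8 cells, to ask what blockade does without CD4 cells. Ccpg1 rose to 26.7 ± 14.8 CPM from 0.0565 ± 0.0669 CPM (log2 8.44 ± 1.36, adjusted p = 0.0285) and Xist by 9.57 ± 0.79. The Y-linked and mitochondrial genes made up most of the 6 that fell, such as mt-Cytb (-2.26, adjusted p = 0.00312) and mt-Co1 (-1.90, adjusted p = 0.0331). Of 25 lists, 10 were called, 0 with estimated correlation and 2 by fry. Type I interferon genes rose in 23 of 26 (median 1.81, adjusted p = 5.23e-07; 0.107 with estimated correlation). Receptor signalling genes rose in 13 of 18 (1.44, adjusted p = 0.00235; 0.327 with estimated correlation), with the early activation marker Cd69 at 825 against 332 CPM. Costimulation genes rose in 19 of 23 (1.51, adjusted p = 7.05e-05; 0.321 with estimated correlation). Glycolysis genes rose in 12 of 18 (0.38, adjusted p = 0.0452; 0.458 with estimated correlation), with Pkm (1280 against 596 CPM, 1.10 ± 0.27) and Gpi1 (1.05 ± 0.28) passing over the list alone. Lists also rose for cytotoxic effectors (1.00, 14 of 20, adjusted p = 0.0287; Klrg1, 2.72 ± 0.93), interferon gamma (0.95, 20 of 26, 0.00512) and CD8 lineage genes (1.20, 5 of 5, 0.0292), each with adjusted p = 0.458 with estimated correlation. Homing genes (0.82, 10 of 14, adjusted p = 0.0306; 0.327 with estimated correlation) and Th1 genes (1.07, 9 of 13, 0.0240; adjusted p = 0.321 with estimated correlation) rose too. Ccr2 passed over the homing list alone, at 342 against 135 CPM. Mitochondrial genes fell in 7 of 7 (-1.83, adjusted p = 8.07e-09; 0.248 with estimated correlation). In July alone the median was -0.12 for cytotoxic, -0.38 for interferon gamma and -0.38 for CD8 lineage genes. Without isotype mice 1 and 2, 2 lists were called. The interferon gamma median was then -0.32 and the receptor signalling median 0.103. Without isotype 1 alone, every call but type I interferon and mitochondrial genes was lost (adjusted p from 0.0560 for costimulation to 0.814 for cytotoxic). The cytotoxic call was lost without isotype M122 (0.0905) or CD4-depleted M224 (0.0822), 1 (0.0826) or 2 (0.0713), and that of glycolysis without isotype M122 (0.226) or CD4-depleted M224 (0.0858) or 2 (0.0642). CD8 lineage lost its call without CD4-depleted M224 (0.0613), 1 (0.0502) or 2 (0.0790), homing without M224 (0.0589) or 1 (0.131), and interferon gamma (0.0502) and Th1 (0.0799) without CD4-depleted 1. edgeR called 2 genes higher and 6 lower (904 at unadjusted p under 0.05), limma-trend 20, DESeq2 342, June alone 19 and July alone 0. The 8 became 23 without isotype M122, 4 without isotype 1, 2 without CD4-depleted M225, and 3 without isotype 2 or CD4-depleted M224, 1 or 2. The calls of Ccpg1 and mt-Co1 were lost without CD4-depleted M225, 1 or 2 or isotype 1 or 2, and that of mt-Co1 also without M224, with adjusted p from 0.0629 to 0.154.

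In the lymph node, where T cells are primed, ICB was compared with isotype in CD8 cells. Klrg1 (ENSMUSG00000030114), a receptor of terminally differentiated effector cells, rose from 0.888 ± 1.06 CPM (0.0891 to 2.45) to 30.9 ± 11.1 CPM (20.9 to 46.1). The log2 change was 5.06 ± 0.84 (adjusted p = 0.0384), with 5.06 in June and 5.49 in July. Cytotoxic effector genes rose together in 12 of 16 members (median log2 1.25, adjusted p = 0.00141; 0.0490 with estimated correlation). Gzma stood at 472 against 54.0 CPM, Gzmb at 106 against 16.7 CPM and the chemokine gene Ccl5 at 579 against 235 CPM. Klrg1 alone passed over the list alone. Type I interferon genes fell in 18 of 26 (median -1.11, adjusted p = 0.00242; 0.291 with estimated correlation), with the regulator Irf7 at 32.0 against 104 CPM. With members at 0 counts set to their bound the median was -0.95. All 7 mitochondrial genes fell (median -1.24, adjusted p = 2.27e-07; 0.246 with estimated correlation), 6 of them past the test over the list alone. Pdcd1 stood at 46.5 against 12.3 CPM (2.79 ± 1.07, not past the test). Of 11297 genes tested edgeR called 2 higher, Klrg1 and Xist (9.24 ± 0.72), and 5 lower, the Y-linked Ddx3y and Uty, the factor gene Cux2, mt-Rnr2 and mt-Co1. At unadjusted p under 0.05 there were 740, and limma-trend called 15, DESeq2 317, June alone 4 and July alone 0. Without ICB 2 the count was 3. Klrg1 lost its call without isotype M122 (adjusted p = 0.136) or M123 (0.127) or ICB M217 (0.115), M218 (0.0609), 1 (0.0897) or 2 (0.0980). The call of mt-Co1 was lost without isotype M123 or 1 or ICB M217, M218 or 2 (0.0915 to 0.149), and that of the interferon list without isotype 1 (0.162).

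The comparison of CD4-depleted ICB with ICB asks what CD4 cells contribute to CD8 cells in the lymph node. Tnfrsf4 (ENSMUSG00000029075), which encodes OX40, a receptor that sustains activated T cells, rose from 29.8 ± 12.5 CPM (18 to 44.3) under ICB to 496 ± 189 CPM (277 to 696) in CD4-depleted mice. This is a 16.2-fold change (log2 4.02 ± 0.49, adjusted p = 0.00663), with log2 changes of 3.46 in June and 4.66 in July. The regulatory T cell list rose in 15 of 15 members (median log2 1.47, adjusted p = 2.45e-09; 0.00167 with estimated correlation). Of its members 4 passed over the list alone, Tnfrsf4, the factor gene Ikzf2 (584 against 216.6 CPM, 1.39 ± 0.40), the interleukin 2 receptor gene Il2ra (66.5 against 1.05 CPM, 5.71 ± 1.77) and Lrrc32, which presents latent TGF beta (5.75 against 0.0314 CPM). T cell receptor signalling genes rose in 16 of 20 (median 1.61, adjusted p = 0.000143; 0.0303 with estimated correlation). Of the 3 that passed over the list alone, Tnfrsf4 and Il2ra were higher and Irf4, a factor induced by receptor signals, lower (0.0513 against 15.9 CPM). Tnfrsf18, the gene of GITR, stood at 158 against 53.3 CPM. Costimulation genes rose in 15 of 21 (median 0.34, adjusted p = 0.000573; 0.0303 with estimated correlation; Tnfrsf4 passing over the list alone). Follicular helper genes rose in 9 of 12 (median 1.51, or 1.48 with members at 0 counts set to their bound, adjusted p = 0.00438; 0.0322 with estimated correlation). P2rx7, an ATP receptor gene, stood at 17.5 against 0.126 CPM, Icos at 137 against 33.8 CPM and Il21 at least 39.8-fold higher, and 0 members passed over the list alone. CD4 lineage genes rose in 5 of 5 (median 1.98, adjusted p = 0.00193; 0.0339 with estimated correlation; 1 member passing over the list alone). Cd4 (8.15 against 0.0534 CPM) came from July (M225 25.1, M224 7.39 CPM) and not June (0 and 0.103). So did Foxp3 (30.4 and 44.5, against 0.261 and 0 CPM).

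Natural killer (NK) type receptors fell in 6 of 7 in the same comparison (median log2 -2.38, adjusted p = 0.00438; 0.0322 with estimated correlation), with Klrk1, the gene of NKG2D, at 31.8 against 140 CPM and Klrd1 at 25.7 against 68.5 CPM. Naive and memory genes fell in 13 of 16 (median -0.59, adjusted p = 0.0227; 0.163 with estimated correlation), with Ly6c2 at 7.33 against 41.0 CPM. Neither list had a member past the test over the list alone. Pdcd1 stood at 163 against 46.5 CPM (1.62 ± 0.95), Gzmb at 102 against 106 CPM and Klrg1 at 17.2 against 30.9 CPM. The next smallest p-values were those of Gcnt1 (653 against 240 CPM, adjusted p = 0.370), Crebl2 (1035 against 469 CPM, adjusted p = 0.370) and B930095G15Rik (log2 1.99), none past the test. edgeR called Tnfrsf4 alone (579 or 5.13% at unadjusted p under 0.05), limma-trend 1 and DESeq2 238, where a split of these libraries by batch gave 280. June alone gave 0 (Tnfrsf4 log2 3.38, adjusted p = 0.947), July alone 0 (4.57, adjusted p = 0.235) and a fit of the pair of groups alone 0 (3.99, adjusted p = 0.0685). Its call was lost without ICB M217 (adjusted p = 0.0656), M218 (0.0623) or 1 (0.0619) at log2 changes of at least 3.77. The follicular helper call was lost without CD4-depleted 1 (0.325) or 2 (0.103), and the naive call without ICB M218 (0.105) or CD4-depleted M224 (0.0636), 1 (0.0675) or 2 (0.0837).

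CD40 activation added to CD4 depletion went with a cytotoxic program in lymph node CD8 cells. Cytotoxic effector genes rose in 14 of 16 (median log2 1.35, adjusted p = 0.000364; 0.0221 with estimated correlation). Over the list alone Klrg1 (297 against 17.2 CPM, 4.07 ± 0.82) and the granule gene Nkg7 (2003 against 864 CPM, 1.14 ± 0.23) passed. Gzma stood at 504 against 30.3 CPM (3.80 ± 1.42) and Gzmb at 658 against 102 CPM (2.60 ± 1.03). Klrg1 lay between 135 and 378 CPM in the 3 CD40 libraries and between 11.3 and 22.2 CPM in the 4 without CD40 activation (adjusted p = 0.422 over all genes). Gzmb lay between 533 and 784 against 73.0 to 178 CPM (adjusted p = 0.733). NK type receptors rose in 6 of 7 (median 3.35, adjusted p = 0.0025; 0.0405 with estimated correlation). Klrk1 stood at 130 against 31.8 CPM and Klrd1 at 75.2 against 25.7 CPM, with 0 members passing over the list alone. Proliferation genes rose in 24 of 30 (median 0.90, adjusted p = 0.00886; 0.562 with estimated correlation), with Birc5 at 124 against 40.2 CPM. Type I interferon genes rose in 21 of 26 (median 1.44, adjusted p = 0.00468; 0.350 with estimated correlation), with Oas2 at 39.6 against 0.0474 CPM. No member of either list passed over the list alone. Tcf7, a factor of naive and memory cells, stood at 457 against 1134 CPM (-1.22 ± 0.35), Mki67 at 168 against 46.3 CPM (2.08 ± 1.13) and the cytoskeletal gene Synpo at 0.462 against 233.96 CPM (-8.23 ± 1.20, adjusted p = 0.0611). Tgfbr3, a TGF beta coreceptor, stood at 98.2 against 657 CPM (-2.71 ± 0.47, adjusted p = 0.194) and Crebl2 at 400 against 1035 CPM (-1.30 ± 0.24), none past the test. edgeR called 0 genes (757 at unadjusted p under 0.05), limma-trend 1 and DESeq2 375, while 2 lists were called by fry. The count was 2 without CD40 M234. The proliferation call was lost without CD40 M232 (adjusted p = 0.313) or 2 (0.0570) or CD4-depleted 1 (0.101), and the interferon call without CD40 2 (0.0741).

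Against the ICB libraries used above, the same CD40 group libraries had high Tnfrsf4 and cytotoxic genes. Tnfrsf4 rose to 556 ± 192 CPM (363 to 746) from 29.8 ± 12.5 CPM (log2 4.16 ± 0.51, adjusted p = 0.00742), with 3.57 in June and 4.65 in July. Regulatory T cell genes rose in 12 of 15 (median log2 0.43, adjusted p = 0.000519; 0.0477 with estimated correlation). Over the list alone Tnfrsf4, Il2ra (40.7 against 1.05 CPM) and Foxp3, the lineage factor of regulatory T cells (30.4 against 0.795 CPM), passed. Cytotoxic genes rose in 12 of 16 (median 1.29, adjusted p = 0.00935; 0.0681 with estimated correlation). Over the list alone Klrg1 (297 against 30.9 CPM, 3.22 ± 0.80), Nkg7 (0.92 ± 0.23) and Ccl5 (1445 against 579 CPM, 1.33 ± 0.43) passed. Type I interferon genes rose in 19 of 26 (median 1.75, or 1.10 with members at 0 counts at their bound, adjusted p = 0.000519; 0.106 with estimated correlation). Costimulation genes rose in 17 of 21 (median 0.23, adjusted p = 0.000877; 0.0534 with estimated correlation) and CD4 lineage genes in 5 of 5 (1.56, adjusted p = 0.00563; 0.0796 with estimated correlation). Receptor signalling genes (14 of 20, 0.46, adjusted p = 0.00935) and exhaustion genes (12 of 15, 0.30, or 0.70 at the bound, 0.0469) rose, each with adjusted p = 0.106 with estimated correlation. Proliferation genes (22 of 30, 0.63, adjusted p = 0.0270), oxidative phosphorylation genes (18 of 22, 0.39, 0.0270) and mitochondrial genes (7 of 7, 0.50, 0.0469) rose too, with adjusted p = 0.562, 0.562 and 0.567 with estimated correlation. Tcf7 stood at 457 against 1490 CPM (-1.65 ± 0.36, adjusted p = 0.522) and the phosphate transporter gene Slc20a1 at 683 against 1568 CPM. Synpo had a log2 change of -7.16 ± 1.13 (adjusted p = 0.0803), Tgfbr3 of -2.57 ± 0.46 and Gzmb of 2.47 ± 1.03, none past the test. Tnfrsf4 was the only gene edgeR called (658 at unadjusted p under 0.05), limma-trend called 2, DESeq2 319 and June, July or the pair of groups alone 0. Tnfrsf4 lost its call without ICB M217 (adjusted p = 0.0742), M218 (0.0687) or 1 (0.0588) or CD40 M232 (0.0562). Without CD40 M234 the count was 3. Exhaustion lost its call without ICB M217, M218 or 2 or CD40 M232 or 2 (adjusted p 0.0588 to 0.127), and proliferation without ICB M217, M218 or 1 or CD40 M232 or 2 (0.0521 to 0.522). Receptor signalling lost its call without CD40 M234 (0.0868), oxidative phosphorylation without ICB M217 (0.0588) or CD40 M232 (0.204) or M234 (0.106), and mitochondrial genes without ICB M217, M218 or 2 or any CD40 library (0.0715 to 0.255).

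**Figure D3:**
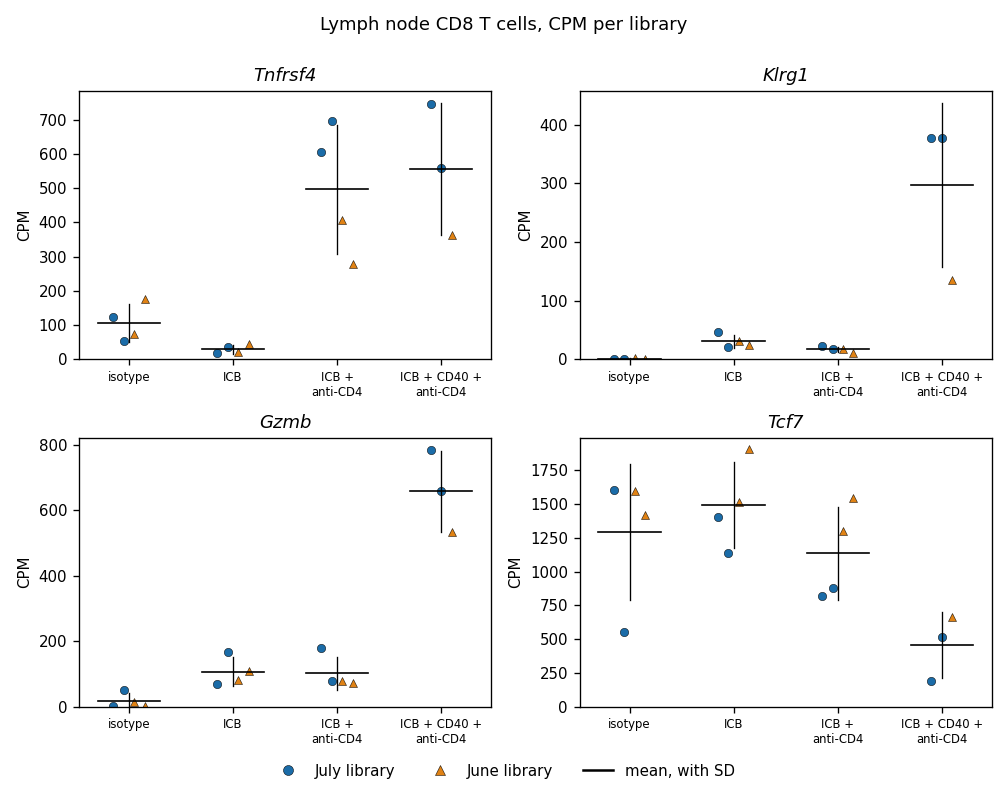
CPM of Tnfrsf4, Klrg1, Gzmb and Tcf7 in each LN CD8 library by treatment, with circles for July, triangles for June, lines for group mean and SD. Tnfrsf4 averages 29.8 CPM under ICB, 496 CPM in CD4-depleted ICB and 556 CPM in the CD40 group, while Klrg1 and Gzmb are highest in the CD40 group.

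Against isotype, the same CD4-depleted LN CD8 libraries had high helper and regulatory genes. Regulatory T cell genes rose in 12 of 15 (median log2 1.82, or 0.98 with members at 0 counts at their bound, adjusted p = 4.88e-05; 0.0226 with estimated correlation). Over the list alone Tnfrsf4 (496 against 107 CPM, 2.17 ± 0.45), Ikzf2 (1.79 ± 0.40) and Ccr8, at least 80.0-fold higher, passed. Follicular helper genes rose in 10 of 12 (median 1.36, adjusted p = 0.001; 0.0282 with estimated correlation). Over the list alone Pdcd1 (163 against 12.3 CPM, 4.41 ± 1.10) and P2rx7 passed. Lists also rose for costimulation (0.88, 18 of 21, adjusted p = 0.00169) and exhaustion (1.08, 9 of 15, 0.0121; Pdcd1 over the list alone), with adjusted p = 0.0516 and 0.0545 with estimated correlation. CD4 lineage (2.28, adjusted p = 0.0198), Th2 and Th17 (1.18, 4 of 5, 0.0303) and cytotoxic genes (0.86, or 0.45 at the bound, 0.0484) rose too, each with adjusted p = 0.109 with estimated correlation. Over the Th2 and Th17 list alone the factor gene Gata3 (2292 against 1089 CPM) and Ccr6 passed, and over the cytotoxic list alone Klrg1 (17.2 against 0.888 CPM) and Ccl5 (908 against 235 CPM). Lists fell for type I interferon (-0.77, 22 of 26, adjusted p = 0.0155), naive and memory (-0.37, 11 of 16, 0.0218) and mitochondrial genes (-1.21, 7 of 7, 9.95e-07; all 7 over the list alone), with adjusted p = 0.199, 0.135 and 0.112 with estimated correlation. edgeR called 1 gene higher, Xist (9.76 ± 0.73), and 5 lower (897 at unadjusted p under 0.05), 6 genes that were also called for ICB against isotype. Limma-trend called 12, DESeq2 425 and July alone 0, and the count was 10 without isotype M122. The exhaustion call was lost without isotype M123 (adjusted p = 0.145), that of interferon without isotype M122 (0.0537) or 1 (0.176) or CD4-depleted 2 (0.0920), and that of naive genes without isotype M122 (0.0643) or 2 (0.205) or CD4-depleted M224 (0.0606). Cytotoxic genes lost theirs without any isotype library or CD4-depleted M224, M225 or 1 (0.0504 to 0.121). CD4 lineage and Th2 and Th17 genes did without isotype M122, M123 or 1 or CD4-depleted M224 (0.0537 to 0.0988), the former also without M225 (0.0552), the latter without CD4-depleted 1 (0.0909). mt-Co1 lost its call without isotype M123, 1 or 2 or any CD4-depleted library (0.0538 to 0.174).

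In CD4 cells, ICB was compared with isotype in each tissue to ask how the helper cells themselves responded. In the tumor, NK type receptor genes rose in 8 of 8 (median log2 3.21, adjusted p = 0.000156; 0.193 with estimated correlation). Klrk1 passed over the list alone (67.2 against 0.811 CPM, 6.40 ± 1.77). Genes of Th1 cells, the helper cells that make interferon gamma, rose in 12 of 13 (median 1.64, adjusted p = 0.00676; 0.281 with estimated correlation). Cytotoxic genes rose in 9 of 13 (1.80, adjusted p = 0.0333; 0.363 with estimated correlation). Tbx21, the Th1 factor, passed over either list alone (31.7 against 0.0517 CPM, 8.65 ± 2.34). Interferon gamma response genes rose in 21 of 26 (1.37, adjusted p = 0.00452; 0.363 with estimated correlation), with the antigen transporter gene Tap1 at 235 against 56.9 CPM. Ifng itself stood at 24.4 against 1.08 CPM (5.45 ± 2.48). Exhaustion genes rose (2.03, 11 of 14, adjusted p = 0.00452) and proliferation genes fell (-0.83, 24 of 30, 0.0046), both with adjusted p = 0.193 with estimated correlation. Costimulation (0.85, 19 of 22, adjusted p = 0.0231) and follicular helper genes (1.44, 6 of 8, 0.0231) rose with adjusted p = 0.436 and 0.363 with estimated correlation. Markers of other cells rose with them, for neutrophils (3.98, 4 of 4, adjusted p = 0.00145), macrophages and monocytes (2.30, 13 of 15, 0.0411) and dendritic cells (2.01, 4 of 5, 0.0461), with adjusted p = 0.193, 0.436 and 0.363 with estimated correlation. Over the list alone Spp1, of the macrophage list, was lower (1125 against 4086 CPM) and the dendritic cell genes H2-Ab1 (399 against 71.8 CPM) and Cd74 (289 against 75.5 CPM) higher. Mitochondrial genes fell in 7 of 7 (-1.02, adjusted p = 0.00515; 4 over the list alone; 0.363 with estimated correlation). Of the 4 isotype libraries 3 were high-ratio, so a fit without them rests on isotype 2 alone.

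Among single genes in tumor CD4 cells, Xist rose (log2 9.88 ± 1.05, adjusted p = 0.00837). The next were Hoxd8 (0.0430 against 83.8 CPM, adjusted p = 0.170), Uty, at least 389-fold lower, and Galnt6 (82.6 against 0.955 CPM, adjusted p = 0.526). Neither these nor Tcf7 (194 against 61.5 CPM, 1.95 ± 0.73), Cd4 (197 against 79.1 CPM, 2.04 ± 0.98), Pdcd1 (147 against 41.2 CPM, 4.17 ± 2.43) or Foxp3 (0.11 ± 0.95) passed. edgeR called 1 gene of 9427 (425 or 4.51% at unadjusted p under 0.05), limma-trend 0, DESeq2 216, and June or July alone 0. Xist lost its call without isotype M122 (adjusted p = 0.0829), isotype 1 (0.0572) or ICB 2 (0.190), and the count was 2 without ICB M217. Without isotype M122 all lists but proliferation, NK, neutrophil and mitochondrial genes lost their calls (adjusted p 0.0724 to 0.472). Calls were also lost without isotype 1 (cytotoxic 0.0716, interferon gamma 0.0602, costimulation 0.175) or ICB M218 (costimulation 0.177, follicular helper 0.103, macrophage 0.12, dendritic 0.103). The same held for ICB M217 (cytotoxic 0.0891), ICB 1 (dendritic 0.121), ICB 2 (macrophage 0.225) and isotype 2 (macrophage 0.319).

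In LN CD4 cells 2 genes were lower under ICB than isotype, as in LN CD8. Sex or ICB can be the source. Ddx3y (ENSMUSG00000069045), a Y-linked helicase gene, fell from 329 ± 193 to 0.0471 ± 0.0943 CPM (log2 -12.73 ± 1.29, adjusted p = 0.00429). Cux2 (ENSMUSG00000042589), a homeobox factor gene, fell from 700 ± 911 to 0.403 ± 0.242 CPM (-10.57 ± 1.00, adjusted p = 0.00429). Xist stood at 130 against 0.140 CPM (adjusted p = 0.187) and 2310022B05Rik had a log2 change of -11.48 (adjusted p = 0.187). Pdcd1 stood at 61.7 against 223 CPM (-1.49 ± 0.83), and Foxp3 and Cd4 had log2 changes of -0.18 ± 0.84 and -0.28, none past the test. No list of 23 was called. edgeR called 0 genes higher and 2 lower of 8084 (204 at unadjusted p under 0.05), limma-trend 0, DESeq2 183, and June or July alone 0.

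Isotype mice give the difference between tumor and lymph node, which can lie in cell content, as 5 tumor libraries were high-ratio. In tumor CD8 cells Lilr4b, a receptor of the immunoglobulin family, rose to 234.4 ± 226 from 0.239 ± 0.230 CPM (log2 9.53 ± 1.41, adjusted p = 0.00122). The heat shock gene Hspa1a rose to 139 ± 94.5 from 0.122 ± 0.186 CPM (10.15 ± 1.64, adjusted p = 0.00273) and Insl6 by 8.22 ± 1.26. Klhl3, an adaptor for protein degradation, fell to 0.518 ± 0.245 from 375 ± 194 CPM (-9.45 ± 1.30, adjusted p = 0.000928). Itgae, the integrin that binds epithelial E-cadherin, fell to 0.404 ± 0.407 from 111 ± 82.4 CPM (-8.08 ± 1.14, adjusted p = 0.00122). Tmem154 (-9.37 ± 1.55), Ccpg1 (-8.76) and Rfx7 (-6.20) fell as well. Pdcd1 rose to 291 from 12.5 CPM (4.82 ± 0.94, adjusted p = 0.0136), Gzmb to 378 from 16.3 CPM (4.41 ± 0.99, adjusted p = 0.0378) and Klrg1 to 16.1 from 0.916 CPM (4.12 ± 0.94, adjusted p = 0.0385). Tcf7 fell to 126 from 1336 CPM (-3.49 ± 0.73, adjusted p = 0.0228). Pdcd1 lost its call without LN 2 (adjusted p = 0.0558) and Gzmb without LN M122, 1 or 2 or tumor M123 or 2 (0.0599 to 0.10). Klrg1 did without LN M122 or 2 or tumor M123 or 2 (0.0555 to 0.165) and Tcf7 without LN M122, 1 or 2 or tumor M123, 1 or 2 (0.0540 to 0.107). Fgl2, at least 312-fold higher, Klri2, Lilrb4a, Cish and Sytl2 rose and Dolpp1, Fam117a and St3gal6 fell, each losing its call without 3 to 7 of the 8 libraries (LN M122 among them, adjusted p up to 0.158). Il7r, Havcr2 and Cd8a had log2 changes of -2.25 ± 0.74, 3.44 ± 1.32 and -0.19, not past the test over all genes.

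By lists, glycolysis genes rose in 17 of 18 in tumor CD8 cells (median log2 2.26, adjusted p = 3.57e-09; 0.0217 with estimated correlation), with 10 past the test over the list alone. Over all genes Ldha (1523 against 571 CPM, 1.42 ± 0.27), Gapdh (2.37 ± 0.46) and Aldoa (2.17 ± 0.46) passed. Those 3 calls were lost without LN 1 or 2, Gapdh and Aldoa also without LN M122 or tumor M123 (adjusted p 0.0565 to 0.0999). Naive and memory genes fell in 12 of 16 (-1.60, adjusted p = 2.22e-05; 0.0217 with estimated correlation), with Tcf7 and Il7r among those passing over the list alone. B cell genes fell in 8 of 9 (-3.26, or -4.49 at the bound, adjusted p = 0.00036; 0.0217 with estimated correlation), with Ighm at 53.9 against 522 CPM. Cytotoxic genes rose in 19 of 21 (1.87, or 2.04 at the bound, adjusted p = 0.000138; 5 over the list alone) and exhaustion genes in 11 of 16 (3.23, 0.000794; over the list alone Pdcd1 and Cd244a), both with adjusted p = 0.0987 with estimated correlation. NK type receptors rose in 10 of 11 (2.58, or 4.01 at the bound, adjusted p = 0.00173; 0.0672 with estimated correlation; 5 over the list alone). Macrophage genes rose in 13 of 13 (2.82, or 4.44 at the bound, adjusted p = 0.00172; 0.310 with estimated correlation), 4 of them over the list alone, among them Cd14 at 62.5 against 0.104 CPM. Stress genes rose in 12 of 20 (0.43, adjusted p = 0.0491; 0.253 with estimated correlation; 5 over the list alone). Lists fell for interferon gamma (-1.02, 19 of 26, adjusted p = 0.000414; Irf9 among those passing over the list alone), type I interferon (-0.89, 18 of 26, 0.0248) and CD8 lineage genes (-1.87, 4 of 5, 0.00352; over the list alone Crtam and Cd8b1), with adjusted p = 0.310, 0.370 and 0.310 with estimated correlation. In July alone the interferon gamma and CD8 lineage medians were 0.14 and 0.67. The LN isotype library M123 held 1824 CPM of Spp1 against 0.178 to 1.53 CPM in the other LN isotype libraries. Its receptor complex RNA was 1877 CPM against 3044 to 3440 CPM. edgeR called 35 genes higher and 34 lower of 13623 (2006 at unadjusted p under 0.05). It called 25 with a block for mouse, limma-trend 432, DESeq2 1218, June alone 341 and July alone 1. Leaving out a library gave 280 (LN M123), about 2.2e+02 (tumor M122), 45 (tumor 1), 35 (tumor 2), 32 (LN M122), 29 (LN 1) or 24 (LN 2). The exhaustion call was lost without tumor M123 (adjusted p = 0.0609) and the interferon gamma and CD8 lineage calls without tumor 1 (0.147 and 0.207). The stress call was lost without tumor M122 (0.167), tumor M123 (0.0975) or LN 1 (0.0624). So were the type I interferon call (LN M122, M123 or 1, tumor 1 or 2, 0.050 to 0.164) and the Cd14 call (LN M122, 1 or 2, tumor 1 or 2, 0.0669 to 0.133).

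In CD4 cells of isotype mice, H2-Ob, a chain that restrains antigen loading, fell to 0.544 ± 0.367 in the tumor from 514 ± 770 CPM in the lymph node (log2 -9.66 ± 1.32, adjusted p = 0.00246). Tubb6, a tubulin gene, rose to 153 ± 55.1 from 0.325 ± 0.268 CPM (8.82 ± 1.25, adjusted p = 0.00296) and Dgat1, an enzyme of fat synthesis, to 167 ± 154 from 0.416 ± 0.334 CPM (8.48 ± 1.13, adjusted p = 0.00237). Tcf7 fell to 54.5 from 1090 CPM (-4.41 ± 0.74, adjusted p = 0.0117, lost without tumor 1 at 0.0762) and Adam8 rose by 7.92 ± 1.38 (lost without LN M122 at 0.0628). Thbs1, Dstn, Plac8, Snapc1, Sema3a and Hsp90aa1 rose and Btla, Gpm6b, Lgals4, Synpo, Rassf2 and Ctse fell, each losing its call without at least 3 of the 8 libraries (adjusted p up to 0.158). LN M122 was among them except for Gpm6b, which was lost without tumor M123, 1 or 2 or LN 1 or 2. Follicular helper genes fell in 12 of 14 (median -3.33, or -3.59 at the bound, adjusted p = 3.23e-07; 0.0107 with estimated correlation; 7 over the list alone). Btla, an inhibitory receptor gene, stood at 0.250 against 139 CPM, Slamf6 changed by -4.51 ± 1.01 and Ascl2 was at least 159-fold lower. Stress genes rose in 15 of 20 (1.78, adjusted p = 0.000856; 0.0244 with estimated correlation; 6 over the list alone), with the chaperone gene Hsp90aa1 at 968 against 191 CPM. Glycolysis genes rose in 15 of 18 (2.23, adjusted p = 6.01e-05; 9 over the list alone) and NK type receptors in 7 of 8 (2.12, 0.0263; 4 over the list alone), with adjusted p = 0.0708 and 0.210 with estimated correlation. Lists fell for interferon gamma (-1.44, 21 of 27, adjusted p = 0.000243; 10 over the list alone), receptor signalling (-1.01, 16 of 20, 0.0152) and CD4 lineage genes (-1.88, 4 of 5, 0.0152), with adjusted p = 0.151, 0.209 and 0.151 with estimated correlation. Of the receptor signalling genes Tnfrsf9 was higher (522 against 29.0 CPM). Other-cell markers moved in the same libraries. Macrophage genes rose in 15 of 15 (3.76, or 5.22 at the bound, adjusted p = 6.93e-06; 7 over the list alone) and B cell genes fell in 7 of 7 (-3.13, 0.000296), both with adjusted p = 0.108 with estimated correlation. Fibroblast and endothelial genes rose in 5 of 6 (4.70, adjusted p = 0.0229; 0.151 with estimated correlation), over the list alone Dcn (138 against 0.0992 CPM) and Col1a2. edgeR called 17 genes higher and 16 lower of 11231 (1644 at unadjusted p under 0.05), 5 of them among the 69 of CD8 cells. It called 40 with a block for mouse, limma-trend 299, DESeq2 1419, June alone 0 and July alone 6. Leaving out a library gave 75 (tumor 2), 20 (LN 1), 17 (LN 2), 16 (LN M122) or 11 (tumor 1) genes. The receptor signalling call was lost without tumor M122 (adjusted p = 0.119) or tumor 1 (0.0544), that of NK receptors without LN M122 (0.0576), LN M123 (0.0874) or tumor M123 (0.132), and that of CD4 lineage genes without tumor M122 (0.0786).

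Whether ICB acted differently on CD8 cells of the tumor and of the lymph node was tested as an interaction. Type I interferon genes had a more positive ICB effect in the tumor, in 24 of 26 members (median difference of log2 changes 2.5, adjusted p = 3.7e-07; 0.0959 with estimated correlation), with 3.03 for Irf7. So had interferon gamma genes (1.31, 21 of 26, adjusted p = 1.13e-05), costimulation genes (1.56, 16 of 23, 1.4e-05) and CD8 lineage genes (1.43, 4 of 5, 0.0341), with adjusted p = 0.359, 0.108 and 0.490 with estimated correlation. The CD8 lineage median was -0.0873 in July alone and -0.29 without tumor isotype mice 1 and 2. Proliferation genes had a more negative one in 29 of 30 (-2.29, adjusted p = 1.13e-05; 0.0990 with estimated correlation). Tmem154 (ENSMUSG00000056498), a membrane protein gene, passed for a difference of 10.50 ± 1.82 (adjusted p = 0.0494). It stood at 46.0 ± 30.2 CPM under ICB and 0.148 ± 0.182 CPM under isotype in the tumor, and at 21.5 ± 22.2 and 108 ± 77.6 CPM in the lymph node. Ncaph (-8.56), Insl6 (-7.83) and Gmip (4.82) did not pass. edgeR called 1 gene of 13623 (1246 at unadjusted p under 0.05), and 0 with a block for mouse. Limma-trend called 6, DESeq2 705, June alone 40, July alone 0 and the fit without tumor isotype mice 1 and 2 called 0. The count was 9 without tumor isotype M122, 8 without LN isotype M123 and 2 without tumor isotype M123. Tmem154 lost its call without any 1 of 12 of the 16 libraries (adjusted p 0.0597 to 0.127), namely ICB M217, ICB 1 and 2 and isotype 1 and 2 of either tissue, LN ICB M218 and LN isotype M122. CD8 lineage genes lost theirs without LN isotype M122, 1 or 2, LN ICB M217 or M218, tumor isotype 1 or 2 or tumor ICB 1 (0.0517 to 0.519).

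The other interaction asked whether ICB acted differently on CD8 and CD4 cells of the tumor. Type I interferon genes had the more positive effect in CD8 cells in 18 of 26 (median difference 1.61, adjusted p = 0.0214; 0.177 with estimated correlation), with Ifit1, which blocks viral RNA, at 197 against 49.0 CPM in CD8 and 4.75 against 35.4 CPM in CD4 cells. NK type receptors (-1.83, 8 of 10, adjusted p = 0.0149; over the list alone Klrk1, -5.22 ± 1.31) and follicular helper genes (-2.80, 8 of 10, 0.0149; Btla, -10.00 ± 4.40) had the more negative effect in CD8 cells, with adjusted p = 0.177 and 0.161 with estimated correlation. So had markers of B cells (-1.94, 3 of 4, adjusted p = 0.0149; over the list alone Igkc), macrophages (-1.87, 13 of 15, 0.0149; 0.91 in July alone) and neutrophils (-3.82, of 4 members, 0.00848), with adjusted p = 0.177, 0.527 and 0.177 with estimated correlation. H2-Ob (-14.09), Gzmk (-7.78), Ctsw (-6.31) and Wwtr1 (-8.60) had the smallest p-values and did not pass. edgeR called 0 genes (799 at unadjusted p under 0.05), limma-trend 0, DESeq2 314 and July alone 5. The count was 2 without CD4 isotype 2 and 1 without CD4 ICB M218 or CD4 ICB 1. List calls were lost for interferon without CD4 isotype M123 or 2, CD8 isotype 1 or 2 or CD8 ICB 1 (adjusted p 0.0621 to 0.0955). NK, follicular helper and B cell genes lost theirs without CD4 isotype M122 (0.107 to 0.122) or CD8 isotype M123 (0.0646 to 0.113), and B cell genes also without CD4 ICB M217 (0.0655). Macrophage genes did without CD8 isotype 1 (0.0955), CD8 ICB 2 (0.0596) or CD4 isotype 2 (0.160).

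**Figure D4:**
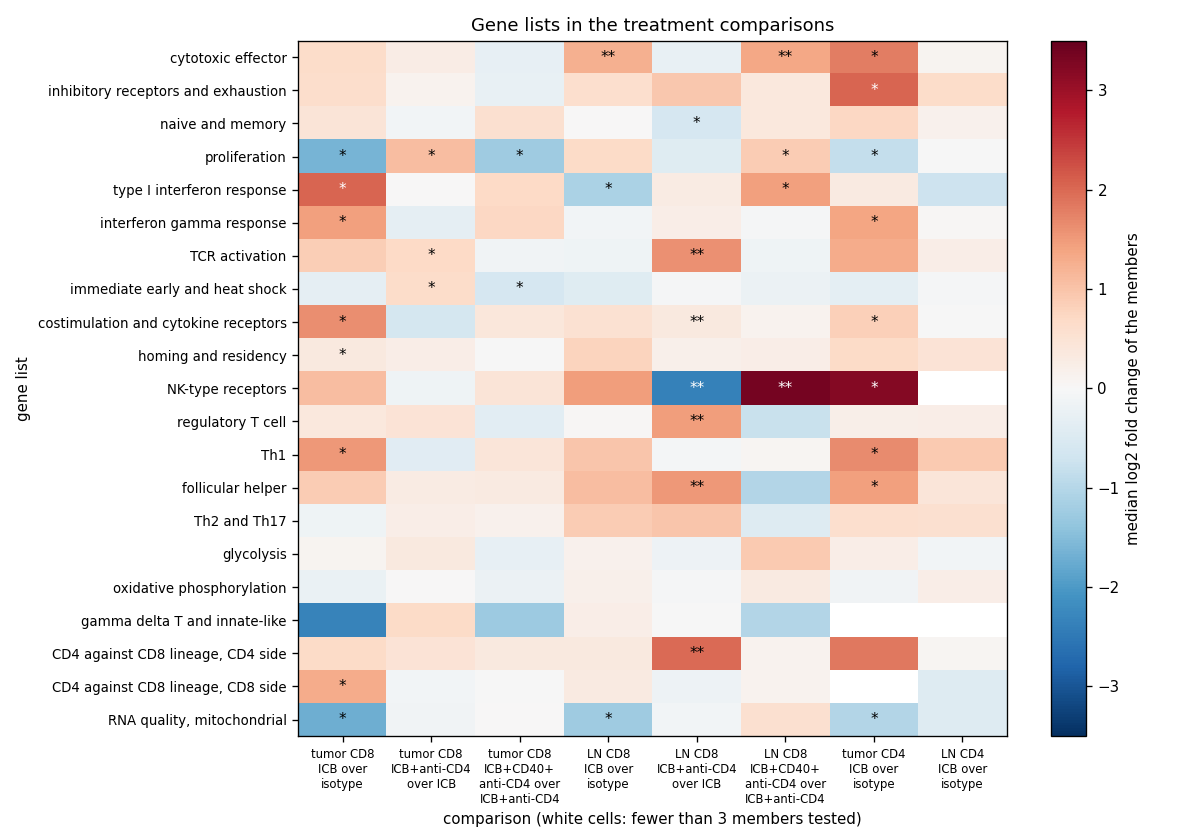
Median log2 fold change of the members of each gene list (rows) in the treatment comparisons (columns), as a colour scale, with * for lists called by camera and ** for those also called with estimated correlation, and white for fewer than 3 tested members. The regulatory T cell list is 1.47 for CD4-depleted ICB against ICB in LN CD8 cells and the proliferation list -1.63 for ICB against isotype in tumor CD8 cells.

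Whether the effect of CD40 activation resembled that of ICB was asked across genes. Across the 11292 genes tested in tumor CD8 cells, which are not independent replicates, the log2 changes of CD40 activation over CD4 depletion correlated with those of ICB over isotype at Pearson r = 0.136 and Spearman rho = 0.142. The two-sided permutation p was 0.0495 for each, from 100 of 1296 regroupings of the libraries (adjusted p = 0.0990 over both tissues). Within batches r was 0.127 in June (p = 0.111) and 0.0462 in July (p = 0.222), and without isotype mice 1 and 2 it was 0.0608 (p = 0.0594), all by permutation. The permutation p was above 0.05 without CD40 M232 or M234 or CD4-depleted 1 (0.0594 each), CD4-depleted 2 (0.0693, r = 0.0870), CD40 2 (0.0891) or CD40 1 (0.119, r = 0.0798). In lymph node CD8 cells, over 11297 genes, r was 0.0152 (permutation p = 0.416) and rho 0.00821 (permutation p = 0.713).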

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

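The tests of explanations in this part were chosen after the results were seen, except the counts of other splits of the libraries, which were planned.

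Every treated mouse had RNA of female and every isotype mouse RNA of male cells. The libraries of all 15 mice with more than 1 library had a single class, the separation held in each of the 2 batches and 0 libraries went against their treatment, which argues against a batch or single swapped labels. A candidate explanation is that the mice of the isotype groups were male and the others female. With 0 isotype mice of the other class, sex and treatment cannot be told apart as the source of any difference between isotype and treated mice, while comparisons among treated mice are free of it.

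Some isotype tumor libraries had less T cell receptor RNA than ICB libraries, while CD8 isotype M123 (5170 CPM) and CD4 isotype 2 (2408 CPM) had more than any of them. Other T cell genes were higher under ICB as well, by a median log2 of 0.96 in CD8 cells (23 of 24 genes) and 1.22 in CD4 cells (24 of 24), so RNA from cells that lack T cell genes may make up more of those isotype libraries. Mitochondrial genes and Actb taking counts do not account for the whole of it, since the log2 ratio of mean log levels was 1.34 in CD8 and 1.25 in CD4 cells and still 1.19 and 1.15 per count outside those genes. In CD8 cells the ratio rests on isotype 1, without which it was 0.422, and 0.295 outside those genes. Macrophages cannot be told apart from other sources. In CD8 cells their list had a median of -0.82 (4 of 12 higher, interval -3.74 to 0.04) and a summed RNA of log2 -1.09, or 0.0685 without Spp1. In CD4 cells it was higher under ICB (median 1.09 of fold changes), but its summed RNA was lower (log2 -0.324), or higher (0.937) without Spp1. Tumor CD8 isotype 1 also held Sdc4 at 18898, Pdpn at 6376 and Spp1 at 5478 CPM, and no cell of origin was tested.

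Tnfrsf4 was higher in LN CD8 cells of CD4-depleted mice than under ICB. Remaining CD4 T cells, in which it stood at 1101 CPM, would have had to bring 111 CPM of Cd4 against a mean of 7.80 and a maximum of 24 CPM observed, which argues against them as the source of the whole rise. Scaling is argued against by the counts before any scaling, at least 3189 in each CD4-depleted and at most 649 in each ICB library. Their log2 change was 3.69 ± 0.56 against 4.02 ± 0.49, not past the test (adjusted p = 0.0787) as the change was smaller and its error larger, while the median gene moved by -0.36. A subset of cells with another ratio of Tnfrsf4 to Cd4, or a change in CD8 cells themselves, may be the source.

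Of 35 splits the real one alone gave the most genes (share 1 of 35, unadjusted) in some comparisons. Against isotype these were tumor CD8 ICB (4 genes, highest other 0) and CD4-depleted (8, 1), LN CD8 ICB (7, 1) and CD4-depleted (6, 0). Others were LN CD4 (2, 0, 34 splits) and, against ICB by Tnfrsf4 alone, LN CD8 CD4-depleted (1, 0) and CD40 (1, 0). With isotype, only the real split follows Xist, so sex and treatment cannot be told apart. With limma-trend 7 of 35 splits gave as many genes (1) for LN CD8 CD4-depleted against ICB. Chance was not excluded for tumor CD4 (1 gene, highest other 1, 2 of 34 splits) or the tissue interaction (1, 1, 6 of 35). Nor was it for the counts of 0, where all 35 splits gave as many (highest other 0, 2 and 1 in tumor CD8, 1 in LN CD8 and 1 in the cell interaction). The tissue comparisons pair libraries by mouse, and the 8 splits that part every pair are too few for a share under 0.05 (CD8 69 genes, highest other 164, 2 of 8; CD4 33, 0, 1 of 8; lists 11, 10, 1 of 8 and 10, 12, 2 of 8). In CD8 tissue splits with 221 and 164 genes both put LN isotype M123 with tumor libraries, which points to a structure of the samples. DESeq2 gave up to 359, 280 and 344 genes on other splits (medians 69.5, 172 and 246) for tumor CD8 ICB against isotype (real 492) and LN CD8 CD4-depleted against ICB (238, reached by 2 of 35) and CD40 against CD4-depleted (375).

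In LN CD8 cells chance was less likely for the list counts against ICB of CD4-depleted (7, highest other 4) and CD40 mice (10, 7). So it was for CD4-depleted against isotype (10, 6). This does not hold for each list, since 6 of those 7, 6 of 10 and 7 of 10 had their smallest p in the real split alone, while 4 of 35 splits matched NK type receptors in the first and 11 proliferation in the second. It was not excluded for tumor CD8 ICB against isotype (8, 14, 9 splits), CD4-depleted against ICB (3, 3, 3 splits), CD40 against CD4-depleted (2, 8, 20 splits) and against ICB (3, 6, 4 splits), CD4-depleted against isotype (10, 15, 8 splits), LN CD8 ICB against isotype (3, 4, 5 splits) and CD40 against CD4-depleted (4, 4, 3 splits), tumor CD4 (12, 15, 3 splits), LN CD4 (0, 2, 34 splits) or the interactions (5, 9, 12 splits; 6, 12, 14 splits). Splits by batch gave 8 and 6 lists in the tumor CD8 CD40 comparisons, 11 in CD8 tissue and 8 and 11 in the interactions, where a block gave 2, 1, 10, 4 and 4.

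A library stood far from the other 3 of its group in 16 of 174 groups and measures, where chance gives about 9 and 1 gene was taken out of the search after its result was seen. In tumor CD4 cells these were ICB M218 with 4.00% mitochondrial counts (4.66 to 4.79), ICB 2 with Xist at 281 CPM (139 to 160) and Cxcr5 at 42.7 CPM (0 to 0.143), and isotype 2 with Pdcd1 at 166 CPM (0.307 to 0.801). In tumor CD8 cells these were ICB 2 with Gzmb at 298 CPM (457 to 473) and Mki67 at 55.1 CPM (0.458 to 8.48), isotype M122 with Tcf7 at 386 CPM (13.4 to 42.9), CD40 M234 with Ifng at 83.5 CPM (24.6 to 31.2) and CD40 M232 with Tnfrsf4 at 1094 CPM (622 to 671). In LN CD8 cells these were CD4-depleted M224 with Gzmb at 172 CPM (70.4 to 76.7) and Mki67 at 103 CPM (20.0 to 29.9), isotype M122 with Ifng at 71.7 CPM (1.17 to 2.41), and ICB 1 with Cd8a at 352 CPM (238 to 248) and Ccr2 at 63.5 CPM (187 to 200.2). In LN CD4 cells these were isotype 2 with 1413 CPM of Y-linked RNA (431 to 575) and ICB 1 with Tbx21 at 114 CPM (0.209 to 14.6). Outside this search, tumor CD4 ICB M217 held Cd8a at 41.5 CPM (others 0.208 to 0.299) and Y-linked RNA at 17.2 CPM (0.0694 to 0.225).

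The ICB effect was called as different between tumor and lymph node CD8 cells for Tmem154 (log2 difference 10.50) and the lists of proliferation (-2.29), type I interferon (2.5), interferon gamma (1.31), costimulation (1.56) and CD8 lineage genes (1.43). With estimated correlation 0 of these lists were called (adjusted p 0.0959 to 0.490) and 12 of 35 splits gave as many. So it was between tumor CD8 and CD4 cells for type I interferon (1.61), NK type receptors (-1.83), follicular helper (-2.80), B cell (-1.94), macrophage (-1.87) and neutrophil genes (-3.82). Here too 0 lists were called with estimated correlation and 14 of 35 splits gave as many. The library labelled LN CD4 after ICB and CD40 activation (16099449 counts) held 3 counts of Cd4, 3566 of Cd8a and 8857 of Cd8b1, with Gzmb at 531 and Klrg1 at 368 CPM, which goes against its label.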

How the results depend on the processing

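Limma-trend, leaving out the high-ratio libraries, and list tests with a block, by batch and without each library were chosen after the results were seen. Of 2692 alternative values of the 165 genes and lists called, 1829 kept direction and call, 840 kept direction and lost the call and 23 reversed in the direction of the test (8 of them lists whose median kept its sign, since camera sets a list against the other genes); of 9542 of the 559 others, 331 gained a call. RLE scaling moved the median gene by less than 0.1 on the log2 scale. The cause was not tested where no smaller number of libraries or larger number of genes explains a shift.

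Comparisons follow in the order tumor CD8 ICB against isotype, CD4-depleted against ICB, CD40 against CD4-depleted, CD40 against ICB and CD4-depleted against isotype, the same 5 in LN CD8, tumor CD4, LN CD4, CD8 tissue, CD4 tissue, tissue interaction and cell interaction. DESeq2 called 492, 251, 288, about 2.2e+02 (94 higher and 124 lower), 342, 317, 238, 375, 319, 425, 216, 183, 1218, 1419, 705 and 314 genes. Without a filter on low counts 103, 10, 8, 5, 65, 55, 10, 42, 30, 72, 31, 13, 242, 192, 63 and 17 were called. Limma-trend called 39, 3, 0, 1, 20, 15, 1, 1, 2, 12, 0, 0, 432, 299, 6 and 0. Camera with estimated correlation called 0, 0, 0, 0, 0, 1, 6, 2, 1, 2, 0, 0, 3, 2, 0 and 0 lists, 17 in all, and fry 5, 0, 0, 0 and 2 in tumor CD8, 2 and 4 in LN CD8 for CD40 against CD4-depleted and ICB, 0 in tumor CD4, 1 and 0 in the interactions, 53 in all.

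Without a batch term the count was 20 (tumor CD8 ICB against isotype), 1 (LN CD8 CD40 against CD4-depleted), 3 (tumor CD4) and 2 (tissue interaction), the last also with RLE. June alone gave 24 and 19 for tumor CD8 ICB and CD4-depleted against isotype, 4 for LN CD8 ICB against isotype, 0 for LN CD8 CD4-depleted and CD40 against ICB, 0 for tumor CD4, LN CD4 and CD4 tissue, 341 for CD8 tissue, 40 for the tissue interaction and a tumor correlation of 0.127. July alone gave 0 for each treatment comparison with calls and for the tissue interaction, 1 for CD8 tissue, 6 for CD4 tissue, 5 for the cell interaction and a correlation of 0.0462. The compared groups alone gave 2 and 1 for tumor CD8 ICB and CD4-depleted against isotype and 0 for LN CD8 CD4-depleted and CD40 against ICB. A replicate block gave 1 list for tumor CD8 CD40 against ICB, 2 genes for tumor CD8 CD4-depleted against isotype, 25 genes for CD8 tissue and 0 for the tissue interaction.

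Without the libraries low in T cell receptor RNA, 2, 5 and 2 lists were called for tumor CD8 ICB against isotype, CD4-depleted against ICB and against isotype, 2 for tumor CD4, 5 for CD4 tissue and 3 for the cell interaction, with 4 genes for tumor CD8 CD4-depleted against isotype, 5 for tumor CD4, 8 for CD4 tissue, 0 and 18 for the interactions, and a correlation of 0.0608. In tumor CD4, CD4 tissue and the cell interaction this leaves tumor CD4 isotype 2 alone in its group, assumed to vary like the others, and is no group test. The camera test reversed there for interferon gamma (median -0.0732) and CD8 lineage (0.0346) in tumor CD8 ICB against isotype, cytotoxic (0.21), interferon gamma (-0.32), receptor signalling (0.103) and CD8 lineage (-0.0662) in CD4-depleted against isotype, cytotoxic (0.24), costimulation (-0.56) and follicular helper (-0.30) in tumor CD4, interferon gamma (0.19) and CD8 lineage (0.23) in CD8 tissue and CD8 lineage (-0.29) in the tissue interaction. In July alone it reversed for interferon gamma (0.0691) and CD8 lineage (0.14) in tumor CD8 ICB against isotype, cytotoxic (-0.12), interferon gamma (-0.38), receptor signalling (0.15), Th1 (0.35) and CD8 lineage (-0.38) in CD4-depleted against isotype, interferon gamma (0.14) and CD8 lineage (0.67) in CD8 tissue, CD8 lineage (-0.0873) in the tissue interaction and macrophage genes (0.91) in the cell interaction.

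Leaving out each library gave gene counts of 2 to 33, 0, 0, 0 and 2 to 23 in tumor CD8, 3 to 10, 0 to 1, 0 to 2, 0 to 3 and 4 to 10 in LN CD8, 0 to 2, 2 to 3, 24 to 280, 11 to 75, 0 to 9 and 0 to 2, and list counts of 6 to 12, 3 to 4, 2 to 4, 1 to 3 and 2 to 14, 2 to 5, 5 to 7, 2 to 5, 6 to 9 and 5 to 10, 4 to 16, 0 to 1, 8 to 11, 8 to 13, 4 to 7 and 4 to 9. The correlations ran from 0.0798 to 0.157 in tumor and from -0.00495 to 0.0327 in LN CD8 cells.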

Other observations

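In LN CD8 cells of isotype mouse M123, expression stood between that of the tissues. On a score of 100 genes per direction that separate tumor from LN in the CD8 libraries of treated mice (0.89 to 1.97 in 12 tumor and -4.73 to -3.72 in 11 LN libraries), it scored -1.51, the other LN isotype libraries -4.95 to -4.08 and the tumor isotype libraries 0.27 to 2.03. It held Sdc4 at 3275 CPM against 15.9 to 388 CPM in the other LN isotype libraries, Lck, the kinase of the T cell receptor, at 1172 against 1882 to 3886 CPM, and Foxp3 at 20.1 CPM.

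Gene lists of gamma delta T cells (smallest adjusted p = 0.0835 over the comparisons), tumor epithelium (0.223) and keratinocytes (0.745) were called in no comparison by camera, and those of plasma cells and erythroid cells never had 3 members past the filter.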
